A study of Arabidopsis thaliana with 6 samples.

How the data were processed

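Total RNA from whole Arabidopsis thaliana seedlings aged 12 days was measured on 6 one-colour Agilent oligonucleotide arrays, 3 for wild type (WT) and 3 for the fun30 mutant. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separately grown plants, so the p-values measure the spread between these samples, which may be technical. RNA was amplified and labelled with the dye Cy3, per the labels' protocols.

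The deposited scanner files hold spot intensity, subtracted for background and detrended within each array by Agilent Feature Extraction, per the file headers. The headers give version 10.7.1.1 of that software, whereas the submitters' processing notes give version 9.1. The same deposited files hold the mean spot intensity and the median local background intensity, without correction. The deposited value table of the whole series holds log2 values for 72945 probes. Its scale was found by comparison with the scanner files: each column correlated at 0.9988 or above with the log2 intensity of its own array, and at 0.9915 or below with any other array. Its medians were 4.39 in all 6 columns and sorted values of the columns differed by at most 0.023, as quantile normalization gives. The values were not centred per probe, and no direction is involved, since they are levels. No step that the authors took between scanner files and value table is stated in the sources used here.

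The array carried 72946 probes of 60 bases, of which 43603 have identifiers that start with A_84 and 29343 have identifiers that start with ATH. Most probes were printed as 2 spots (43583 probes) or 3 spots (29323 probes). These counts nearly equal the numbers of A_84 and ATH probes, so the series may differ in spots per probe. Spots were not counted by series. The gene name and systematic name fields of the files repeat the probe identifier for all 72946 probes, so the files do not pair probes with genes, and no probe-to-gene table or genome sequence was used here. The reference table names loci (assembly TAIR10.1) but matched 0 of the probe identifiers. For this reason the planned measurement of the FUN30-family gene itself, the fixed gene lists, the transposable element genes and the neighbouring genes could not be computed. The fixed rule for naming genes skips probes without a gene name. The 4 probes named in the text were therefore chosen after their values were seen. They are the probe with the largest difference in each direction among called probes well above background on all 6 arrays with non-overlapping groups, and the probe with the largest lower bound in each direction among called probes well above background on all 3 arrays of one group and on none of the other.

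The main values were log2 of the processed signal minus log2 of each array's 75th percentile over non-control spots. Control spots and spots marked by Feature Extraction as non-uniform or as population outliers were left out, and the remaining spots of a probe were averaged on the log2 scale. Between 1643 and 1784 of 175535 non-control spots were left out in this way on each array, and 0 spots were saturated. A probe counted as well above background on an array if at least 50.0% of its remaining spots carried that mark, and it was tested if this held on all 3 arrays of at least one genotype. Each tested probe was a feature of its own, which is also what the planned rule of testing every probe separately gives. Differences are fun30 minus WT. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Lower bounds set the mean of the bright group against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

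The fit was run on simulated data for the fun30 and WT comparison, drawn for 42713 probes with their measured means. Each probe had its moderated SD from the fit, the same in both genotypes. Probes were drawn independently, without a slide difference. The fit recovered 75.0% of 100 probes changed by 1 on the log2 scale and 96.0% of 100 probes changed by 2, with 6 unchanged probes among 177 calls. The real arrays depart from these settings, so this does not estimate the error among the real calls. To see whether probes for the same RNA gave the same answer, probe sequences were compared with one another in Python 3.11.15. Probes that shared an end-to-end overlap of at least 25 identical bases on the same strand were joined into clusters, and pairs whose overlap lay on complementary strands were recorded separately. Intervals of shares are Wilson 95% intervals.

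Array signal over background sets the precision here, together with the number of arrays. All 3 WT arrays lay on slide 1 and were read in scan 1, and all 3 fun30 arrays lay on slide 2 and were read in scan 2. Slide and genotype cannot be told apart, and no fit with the slide as a block was possible. Alternatives covered quantile normalization, median centring, normexp background correction with an offset of 50 followed by quantile normalization, the deposited log2 values, other filters, variance models and thresholds, array weights, a replicate block and the omission of each array. These were chosen before the data were examined. Removal of trends with GC content and signal, a filter requiring all spots well above background, and 1 probe per sequence cluster were added after seeing the data.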

Results

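The series measured RNA levels in whole 12-day-old Arabidopsis seedlings of 2 genotypes, WT and a mutant named fun30, to find transcripts whose level differs in the mutant. Fun30 proteins are a family of SNF2-type chromatin remodelling ATPases, first described in budding yeast, and CHR19 is the Arabidopsis member of that family. There were 3 arrays of each genotype and no other groups. Between 54.9% and 57.6% of the spots were well above background on the WT arrays, and between 51.8% and 54.5% on the fun30 arrays. Every fun30 array thus lay below every WT array in this share. The 75th percentile of the processed signal lay between 85.9 and 104.5 intensity units on the WT arrays and between 102.4 and 111.1 units on the fun30 arrays.

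Across the 42713 tested probes with a value on every array, the WT arrays correlated with one another at 0.992 to 0.993 and the fun30 arrays at 0.976 to 0.992. Correlations between a WT and a fun30 array were lower, from 0.934 to 0.972. The first principal component held 77.7% of the variance and separated the genotypes, with scores of -75.4, -53.5 and -70.7 on the WT arrays and of 31.2, 69.3 and 99.2 on fun30 arrays 1, 2 and 3, so the fun30 arrays also differed widely among themselves on it. The median standard deviation among 3 arrays was 0.11 on the log2 scale in WT and 0.15 in fun30. No 2 arrays held identical values. Because each genotype was hybridised on a slide of its own, every difference below is a difference between genotypes and between slides at once.

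Of 72946 probes, 42738 were tested, and 16132 of these (37.7%) differed between fun30 and WT in limma at an adjusted p under 0.05. The signal was higher in fun30 for 8227 probes and lower for 7905. The median size of the difference among called probes was 0.67 on the log2 scale. A fitted difference of at least 2-fold was found for 1540 probes that rose and 2645 that fell, and one of at least 4-fold for 193 that rose and 357 that fell. These counts include called probes that were not well above background in one genotype, whose fitted folds are uncertain. The 3 fun30 values lay entirely above or below the 3 WT values for 54.3% of tested probes, where chance gives 10% for 3 arrays against 3. The balance of the directions depended on the scaling: with each array centred on its median, which moved the median difference of all tested probes to 0.23, 14403 probes were higher and 4860 lower, so that 74.8% of calls were higher in place of 51.0%. The count of calls fell to 9418 without WT replicate 1, to 9942 without WT replicate 3 and to 9690 without fun30 replicate 2.

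Among the 38137 tested probes that were well above background on all 6 arrays, 7559 rose and 5839 fell. The largest measured rise was that of probe A_84_P813757, with the sequence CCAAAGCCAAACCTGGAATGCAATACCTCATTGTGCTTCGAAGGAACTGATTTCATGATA. Its normalised log2 signal was -1.36 ± 0.13 (SD, n = 3) in WT and 3.48 ± 0.11 (SD, n = 3) in fun30. The difference of 4.84 (SE 0.10) amounts to a 28.6-fold higher signal in fun30, with a limma adjusted p of 7.1e-06. The largest measured fall was that of probe A_84_P11480, with the sequence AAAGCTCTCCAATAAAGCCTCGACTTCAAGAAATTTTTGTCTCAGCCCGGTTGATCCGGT. Its normalised log2 signal was 1.41 ± 0.099 (SD, n = 3) in WT and -1.65 ± 0.24 (SD, n = 3) in fun30. It fell by 3.06 on the log2 scale (SE 0.14), an 8.31-fold lower signal, with a limma adjusted p of 9.4e-05. With normexp correction followed by quantile normalization the sizes were smaller, 12.0-fold for the rise and 3.63-fold for the fall. The genes, chromosomal positions and transcript parts that these probes target are not paired with them in the files, and neither sequence overlapped another probe of the array on the same strand.

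A second class of called probes was well above background in only one genotype. It held 272 probes that were well above background on all 3 fun30 arrays and on none of the WT arrays, and 851 probes with the opposite pattern. Every fun30 array had fewer probes well above background (41100 to 42873) than every WT array (43261 to 45096). The imbalance of 272 against 851 was not separated from this lower detection on the fun30 slide. For both sets a lower bound of the difference was computed in place of a fold from the fit. It reached 4-fold for 33 of the 272 and 85 of the 851. The largest bound upward belonged to probe A_84_P10863, with the sequence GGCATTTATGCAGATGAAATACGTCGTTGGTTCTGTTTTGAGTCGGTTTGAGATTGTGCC. With the main background correction its bound was 64.4-fold higher in fun30, where its normalised log2 signal was 1.95 ± 0.16 (SD, n = 3). The probe was not well above background in WT. Its bound of 6.01 on the log2 scale lay near the fitted difference of 6.32 (limma adjusted p of 0.00033). WT values above the lowest value among probes well above background enter the bound as measured, so it is not a limit of detection. The size depended on the background correction: with normexp and an offset of 50, which is added to every signal and so compresses folds of dim probes, followed by quantile normalization, the difference was 2.75 on the log2 scale, or 6.74-fold. Quantile normalization alone gave 6.41. The largest bound downward belonged to probe A_84_P846029, with the sequence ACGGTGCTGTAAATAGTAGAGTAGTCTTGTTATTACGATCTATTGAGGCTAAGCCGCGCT. It was at least 30.8-fold lower in fun30, where it was not well above background, than in WT, where its normalised log2 signal was 0.55 ± 0.11 (SD, n = 3), with a limma adjusted p of 3.1e-06. With normexp followed by quantile normalization it fell by 1.88 on the log2 scale (a difference of -5.87 with quantile normalization alone), a 3.68-fold lower signal, so both bounds hold for the main background correction alone. Neither probe had an overlapping probe on the same strand.

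**Figure D1:**
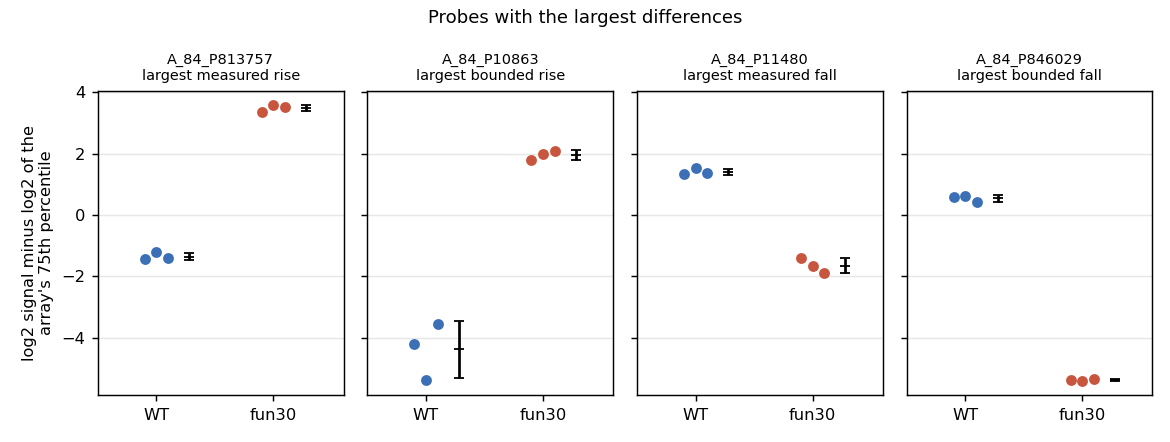
Normalised log2 signal (log2 of the processed signal minus log2 of the array's 75th percentile) of the 4 named probes on each of the 3 WT and 3 fun30 arrays. Points are arrays and the black marks are means with SD. For A_84_P10863 in WT and A_84_P846029 in fun30 the values are not well above background, and the groups do not overlap for any of the 4 probes.

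The 2 series of probes on the array differed in their balance of directions. Of the 31652 tested probes with A_84 identifiers, 6673 rose and 4409 fell, and the median difference was 0.05 on the log2 scale. Of the 11086 tested probes with ATH identifiers, 1554 rose and 3496 fell, and the median difference was -0.24. The ATH median stayed below the A_84 median under each of the scalings tried. The ATH minus A_84 difference of medians was -0.29 on the log2 scale with the 75th percentile or median centring, -0.22 after quantile normalization, -0.21 with the deposited log2 values and -0.091 after normexp correction followed by quantile normalization. With median centring the ATH median itself was -0.0034, and 2604 ATH probes were higher against 2607 lower, while the A_84 median was 0.28 and 11799 A_84 probes were higher against 2253 lower. Probe series also went with signal. When tested probes were divided into 5 equal classes of mean signal, the ATH median was -0.61 and the A_84 median was -0.12 in the dimmest class, and they were 0.098 and 0.089 in the brightest. These are counts over probes, several of which can report on one transcript, and no test of the difference between the series was made across samples. Tested probes include some that were well above background in only 1 genotype. The medians by series and signal class were not computed without them.

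**Figure D2:**
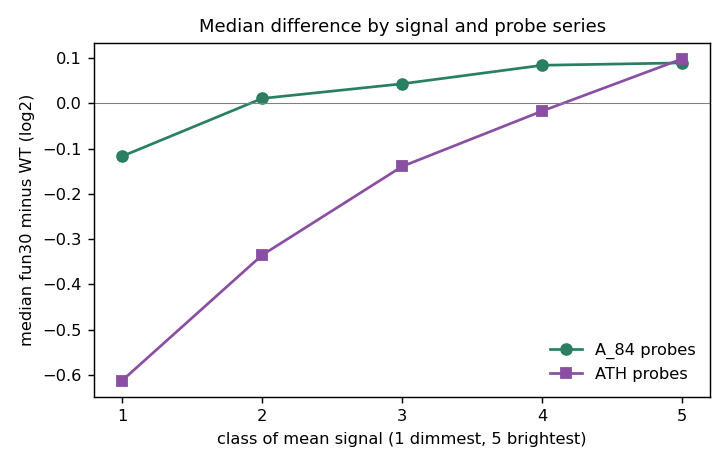
Median fun30 minus WT difference (log2) of tested probes in 5 equal classes of mean signal, from the dimmest (1) to the brightest (5), for A_84 probes (circles) and ATH probes (squares). The ATH medians run from -0.61 in the dimmest class to 0.098 in the brightest, and the A_84 medians from -0.12 to 0.089.

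Overlapping probes showed how far probes with shared bases gave the same difference. Both probes of such a pair lay on the same slides and shared at least 25 bases. A slide difference, or hybridisation of the shared bases, would also make them agree, so their agreement does not bear on these causes. In 5086 tested pairs that overlapped on the same strand, the fun30 minus WT differences of both probes correlated at a Pearson r of 0.88 across pairs and a Spearman rho of 0.88 (permutation p of 1e-04, the smallest that 10000 permutations can give, and 0.00015 after Benjamini-Hochberg adjustment over 3 kinds of pairs). Both probes were called in 1819 of these pairs, and they moved in one direction in 1810, or 99.5% (95% interval 99.1% to 99.7%). Pairs are not independent replicates, since one probe can belong to several pairs. Of 39597 clusters with a tested probe, 1880 held at least 2 tested probes, so most probes had no such partner. Among these 1880 clusters, 1092 held at least 1 called probe. Every tested probe was called higher in 207 and called lower in 330, and probes called in opposite directions occurred in 8. In many of the 1092 clusters, therefore, only part of the overlapping probes was called.

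Probes on complementary strands followed one another far less closely, and the share of them that moved in one direction depended on the scaling. In 379 tested pairs of complementary probes the Pearson r of the differences was -0.045 (permutation p of 0.39, also after adjustment over the 3 kinds of pairs), whereas the Spearman rho was -0.21 (permutation p of 1e-04, the smallest that 10000 permutations can give). With trends in GC content and signal removed from each array, rho was -0.019 (permutation p of 0.71). Both probes were called in 81 pairs, of which 36 moved in one direction, or 44.4% (95% interval 34.1% to 55.3%), and 45 in opposite directions. After quantile normalization 52 of 73 such pairs moved in one direction, or 71.2% (exact binomial p of 0.00037, two-sided), and the share was 71.4% with normexp correction before it and 72.4% with the deposited log2 values, whose columns also share one distribution. It was also 71.0% without WT replicate 1, 65.6% without WT replicate 3, 66.7% without fun30 replicate 2, and 83.3% of 18 pairs at an adjusted p under 0.01. Without fun30 replicate 1, in contrast, the share was 38.0%, or 41 of 108 pairs. The Pearson r lay between -0.12 and 0.18 under all settings tried. With the main scaling, in a further 201 pairs only one of the probes was called.

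**Figure D3:**
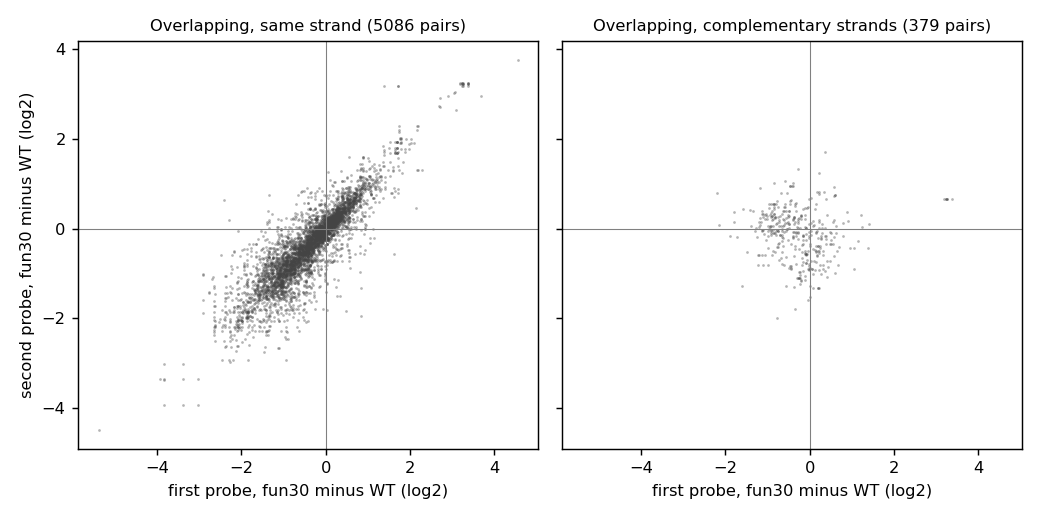
Fun30 minus WT differences (log2) of both probes of each tested pair that overlaps on the same strand (left, 5086 pairs) or on complementary strands (right, 379 pairs), with 1 point per pair. Same-strand pairs lie along the diagonal (r of 0.88), and complementary pairs do not (r of -0.045) with the 75th percentile scaling.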

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

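Of the tests in this part, those on chance, slides, GC content, control probes and the spread among fun30 arrays were chosen after the result they concern had been seen. Among the array's control probes, which are not among the tested probes, 3 were higher on every fun30 array than on every WT array: DCP_1_4 by 0.62, DCP_1_7 by 0.65 and ERCC-00028_121 by 0.51 on the log2 scale. A larger number, 20 of the 27 control sequences above background, were lower on every fun30 array. Many of these carry related names and nearly equal values, so they are not 20 separate measurements.

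A large share of tested probes was called (16132 of 42738): of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many limma calls, and the highest other count was 0 (at most 2893 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Each other split also mixed the genotypes and slides. The difference between them then entered its residual spread, so its count does not measure chance calls. The tables argue against GC content (16203 calls with the GC trend removed), against local surface defects (differences from 2 separate spots of a probe correlated at 0.84 across probes), and against noise peculiar to single sequences (r of 0.70, bootstrap 95% interval 0.33 to 0.92, over 53 pairs of probes in one cluster that share no base). The slide stays open, because it coincides with genotype and the median control probe above background differed by -1.41 between the groups, against a median SD of 0.21 among WT and 0.63 among fun30 arrays (0.49 pooled); the controls' median was -1.42, -1.94 and -2.67 on fun30 arrays 1, 2 and 3, so they also differed within the fun30 slide. A factor that also varies among the fun30 arrays stays open too: the difference between fun30 arrays 3 and 2 correlated at 0.16 across probes with that between fun30 array 1 and WT, between the bounds set for either answer, and the genotype remains untested beside these. Over fun30 arrays 1, 2 and 3 the score on the first principal component rose (31.2, 69.3 and 99.2). In the same order the controls' median, the corner spot brightness (39742, 23713 and 12877 units) and the share of spots well above background (54.5%, 53.1% and 51.8%) fell. With 3 arrays this order was not tested.

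Dim probes were lower in fun30, with a median of -0.31 in the dimmest of 5 equal classes of mean signal. After quantile normalization that median was -0.038, but this normalization forces the arrays to one distribution and so does not decide whether the scaling is the cause. With median centring it was -0.075, which shows that the level of the dim probes depends on the scaling, while their gap to the median of all tested probes was -0.31 both with this and with the 75th percentile scaling, since 1 factor per array shifts all probes alike. Whether less unspecific hybridisation on the fun30 slide contributes stays open. The median control probe was lower by more than the dim probes (-1.41), but many control sequences carry related names and nearly equal values. Of those above background, 20 were lower and 3 higher on every fun30 array. The negative control spots lay between 2.18 and 2.50 units on all 6 arrays. Slide and genotype cannot be told apart here either. Selection by the filter stays open too, since detection in 1 genotype was enough for a probe to be tested. There were 934 tested probes well above background on all WT arrays and no fun30 array, against 307 with the opposite pattern. The dimmest class was not examined without such probes. Over all classes, the median difference was 0.02 among the 38137 probes well above background on all 6 arrays. It was -0.11 over all 72946 probes without the filter.

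ATH probes fell more often than A_84 probes. Lower signal of the ATH probes is not the whole cause: the ATH median lay below the A_84 median by more than 0.05 in 4 of the 5 classes of signal, although the gap was -0.50 in the dimmest class and 0.0091 in the brightest (bootstrap 95% interval -0.023 to 0.041). Nor is a property shared by all ATH probes: in 670 same-strand overlapping pairs of one ATH and one A_84 probe, the median difference between them was -0.0053 (bootstrap 95% interval -0.025 to 0.0097), and in the 226 dimmer of these pairs -0.00048. The 659 ATH probes in such pairs had a median of 0.066 over pairs, against -0.27 for the 10427 ATH probes without an overlapping tested A_84 probe. That those probes report transcripts of another kind is a hypothesis left untested without probe annotation, and the slide stays open.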

How the results depend on the processing

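The 4 named probes kept their direction and stayed past their threshold in each alternative that tested them, with adjusted p up to 0.0094, but their sizes shrank under normexp (offset 50) followed by quantile normalization: A_84_P813757 to 3.59, A_84_P10863 to 2.75, A_84_P11480 to -1.86 and A_84_P846029 to -1.88 on the log2 scale. Of 22 alternatives, 16 kept the count of calls within 1.5 times the main 16132. The others gave 10681 calls (6109 higher, 4572 lower) with ordinary t statistics, 6965 (3905, 3060) at an adjusted p under 0.01, 4185 (1540, 2645) with the 2-fold threshold added, and fewer calls without WT replicate 1, WT replicate 3 or fun30 replicate 2. Stricter thresholds act by construction. For ordinary t statistics and the omitted arrays the cause was not tested, and calls rose to 18619 without fun30 replicate 1. The largest count, 22597 calls (11406 higher, 11191 lower), came with array weights. These weights were uneven in fun30, at 0.45, 3.46 and 0.46 for replicates 1, 2 and 3, against 0.92, 1.02 and 1.49 in WT. Leaving out 1 array gave 9418 to 18619 calls, 5028 to 9054 higher and 4230 to 9565 lower. Median centring gave 14403 higher and 4860 lower, as its shift of 0.23 for all probes entails. The deposited log2 values gave 15743 calls, 13519 of them shared with the main ones, and no shared call changed sign under any alternative. Deviations of same-numbered arrays correlated at 0.31, 0.10 and -0.087. Differently numbered arrays were not compared, so whether array numbers pair the samples stays open. The replicate block gave 14582 calls. GC trend removal, GC and signal trend removal, the all-spots filter and 1 probe per cluster were chosen after seeing the data and gave 14898 to 16203 calls. The share of called complementary pairs moving in one direction left the main interval in 10 of 21 alternatives. Not run, for want of gene names or of a slide shared by genotypes: the mean of probes per gene, camera with an estimated correlation, fry, neighbours within 2 genes and the slide block. Signal over background limits the 272 and 851 probes seen in one genotype to bounds.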

Other observations

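The hypothesis that transcripts from complementary strands are regulated oppositely was tested after the pair values had been seen. Of 81 complementary pairs with both probes called, 45 moved in opposite directions, which an exact binomial test did not separate from an even split (p = 0.37). The majority turned with the scaling, the threshold and the arrays included: 52 of 73 pairs moved in the same direction after quantile normalization (exact binomial p = 0.00037), 60 of 84 with normexp correction before it (p = 0.00011), 55 of 76 with the deposited log2 values, whose columns also share one distribution (p = 0.00012), and 48 of 70 with GC and signal trends removed (p = 0.0025). Without fun30 replicate 1, 67 of 108 moved in opposite directions (exact binomial p = 0.016), whereas 22 of 31 moved in the same direction without WT replicate 1 (exact binomial p = 0.029), 24 of 36 without fun30 replicate 2 (exact binomial p = 0.065) and 15 of 18 at an adjusted p under 0.01 (exact binomial p = 0.0075). These p-values are not adjusted for the settings tried, and no direction is read from them. With the main scaling, the rank correlation over all 379 tested pairs was negative, with a Spearman rho of -0.21 (permutation p of 1e-04, the smallest that 10000 permutations can give, and 2e-04 after adjustment over both rank tests). The probes of a pair differed in mean signal by a median of 3.35 on the log2 scale, and dim probes were lower in fun30. With GC and signal trends removed from each array, rho was -0.019 (permutation p of 0.71), so the negative rank correlation may come from the trend with signal. Pairs share probes and are not independent.

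The brightness of the corner spots, printed as landmarks for the scanner software, was 39036, 29978 and 34263 intensity units on the 3 WT arrays and 39742, 23713 and 12877 units on the 3 fun30 arrays. The negative control spots lay between 2.18 and 2.50 units on all 6 arrays.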
